A study of Homo sapiens with 54 samples.

How the data were processed

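RNA from cultures of H1, an established human embryonic stem cell line, was made into 54 libraries with the Illumina TruSeq RNA kit v2 and sequenced, per the labels' protocols. Cells were exposed to lentivirus for 12 hours on Matrigel and then kept in TeSR1 medium with FGF2, stem cell factor and thrombopoietin. Samples were grouped by the overexpressed factor or factors and the day of collection, as their labels give them, and each library was matched to its column by its title. The growth protocol calls untransduced cells the control, and the series' design text counts 6 control samples, so 5 untransduced libraries and 1 library with a vector for green fluorescent protein formed the control arm.

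The deposited tables held 18430 genes by symbol, in expected counts and in TPM. The expected counts, which are estimates of the reads per gene and need not be whole, were made with RSEM 1.2.3 and Bowtie 0.12.9 after base calling with CASAVA 1.8.2, against hg19, per the submitters' processing notes. The deposited TPM values (shares of the transcripts after scaling for gene length) came from the same program, per the submitters' processing notes. In each library, 30.8% to 51.1% of the genes had an expected count that was not whole, and the TPM of a library summed to between 982689 and 985926. Strand and the treatment of reads shared between similar genes were not given in the sources used here. Levels of near-identical genes (the chorionic gonadotropin beta genes, the pairs HBG1 and HBG2 and HBA1 and HBA2, and the read-through genes GIMAP1-GIMAP5 and ATP5J2-PTCD1) are therefore uncertain one by one. Genes were used by symbol only, and no coordinates are given, because the reference at hand was of another build. A total of 44 genes of the Y chromosome and of X inactivation were left out of every step.

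Expected counts were rounded to whole numbers. Genes with a CPM (the count scaled to a common library total with TMM factors) of at least 1 in at least 2 libraries of a fit were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1, or a slope of at least 0.25 log2 units per day. Every adjusted p of a gene below comes from this test. Total expected counts ran from 7648757 to 33613241 per library, and TMM factors from 0.63 to 1.13. CPM are given as mean ± SD where a group has several libraries. A fold is the ratio of mean CPM. Where the lower group was at 0 the fold is a lower bound against 3 counts over that group, and where it held 1 to 3 counts the ratio is given with a Poisson interval at 95%. Bounds and intervals cover counting error only.

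Comparisons of a group with the controls or with another group at day 5 used 1 fit of all 54 libraries and 15620 genes. Most groups held 1 library, so the spread came from the 6 controls and 4 duplicated groups, which left 9 residual degrees of freedom. A lone library was assumed to vary as these did, and its differences have no replicate check of their own. No source says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The controls cover days 1 to 7, while each overexpression group has its own day. The GATA2 with ETV2 course (7 libraries) and the GATA2, TAL1 and LMO2 course (6 libraries) were compared with day as a factor over 14673 genes with 6 residual degrees of freedom. The GATA2, TAL1 and LMO2 course was compared with the GATA2 and TAL1 course at days 2, 3, 5 and 7 over 14272 genes with 3. In both comparisons the days stood as replicates of a combination. A difference in culture or virus shared by a whole course therefore cannot be told apart from the factors. Trends per day were fitted in the first 2 courses and in the untransduced cells (14295, 13938 and 13498 genes).

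Groups, comparisons, thresholds, gene lists and alternatives were fixed before the data were examined, except where an alternative or test is said to be chosen later. Genes were named by rule: the overexpressed factors; the 8 largest rises and 4 largest falls among called genes with a mean TPM of at least 5 in the higher group and no overlap between the groups' libraries; up to 4 called members of each list; and, in a list with none called, up to 2 members with the highest TPM. For factors in 1 library, up to 4 called endothelial or hematopoietic members with the largest rise were taken. The 22 lists cover pluripotency, primitive streak and mesoderm, endoderm, neuroectoderm, trophoblast, mesenchyme and smooth muscle, cardiac and skeletal muscle, endothelium, artery, vein and lymphatics, hematopoietic regulators, surface and cytoplasmic proteins shared by blood cells, erythroid, megakaryocyte, myeloid, mast cell with eosinophil and basophil, and lymphoid genes, the HOXA cluster, proliferation, p53 and stress, interferon response, and histone genes without a poly(A) tail as a sign of RNA quality. Of their 396 genes 395 matched a symbol, some through older names, and some genes stand in more than 1 list. The factor that was overexpressed was taken out of a list before its test. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members move together one way and compares them with no other genes. Adjustment ran over the 22 lists and 11 comparisons. Counts of members are also given as adjusted over the list alone.

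The alternatives were median-ratio size factors, no filter on low counts, limma on log2(TPM + 1), DESeq2 1.42.0, controls of the same day, the untransduced day 7 pair as controls, a replicate block, courses without the day term or without day 7, and every library left out in turn. On simulated counts with 200 changed genes per comparison, 2 libraries against 6 controls gave calls for 5.97%, 70.1% and 97% of genes changed by 1, 2 and 3 log2 units, and 1 library against 6 controls for 2.99%, 26.9% and 71.2%. The comparison of the courses with ETV2 and with TAL1 and LMO2 recovered 31.3%, 100% and 100%, and that of the courses with and without LMO2 2.99%, 67.2% and 90.9%. Small changes were therefore rarely detectable at this replication. Apart from the set changes, a simulated gene had the same level in all libraries and a spread set by its level alone. Recovery in the real data can therefore be lower, and a gene that was not called may still have changed by a large amount. Figures were drawn with matplotlib 3.10.9.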

Results

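The series asks which transcriptional regulators switch on the program shared by blood and vessel precursors in human pluripotent stem cells. Gene expression was measured by RNA sequencing in H1 cells after lentiviral overexpression of regulators of blood and endothelial development. By their labels, the 54 libraries fell into 6 controls and 48 overexpression samples. The controls were untransduced cells at days 1, 3 and 5 (1 library each) and day 7 (2 libraries), and cells with a vector for green fluorescent protein at day 7. The labels name 27 factors introduced alone, 24 of them in 1 library and TAL1, GATA2 and ETV2 in 2 libraries each, collected 3 or 5 days after transduction. GATA2 was combined with ETV2 (7 libraries over days 1 to 5 and 7), with TAL1 and LMO2 (6 libraries over the same days, the last from floating cells), with TAL1 (4 libraries at days 2, 3, 5 and 7) and with ERG (1 library at day 7). Total expected counts ran from 7648757 to 33613241 per library.

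The overexpressed genes were examined first, as a check of the labels. The reads of a vector and of the cell's own gene were not separated. Of 68 pairs of a factor and its library or group, 65 lay above every control and 63 were called higher. RUNX1 reached 1480 CPM in the library labelled RUNX1a and 1110 CPM in that labelled RUNX1c, against 0.508 ± 0.276 CPM (SD, n = 6) in the controls. LYL1 reached 1670 CPM against 0.696 ± 0.313. In the library labelled GFI, GFI1 stood at 147 CPM, 688-fold above the controls, and GFI1B was listed at 0. The library labelled CBFb held 25.2 CPM of CBFB against 26.8 ± 7.59 in the controls, and the library labelled HES1 held 16.3 CPM of HES1 against 13.9 ± 6.72. LMO2 alone reached 14 CPM against 1.69 ± 0.474, which was not called.

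The duplicated groups differed in how well their libraries matched. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.97 between the TAL1 libraries, 0.964 between the untransduced day 7 libraries, 0.953 between the ETV2 libraries and 0.928 between the day 7 libraries of GATA2 with ETV2. The GATA2 libraries correlated at 0.822, and 3130 genes differed at least 4-fold between them, against 311 to 1029 in the other pairs. GATA2 itself stood at 174 CPM in replicate 1 and 6400 CPM in replicate 2, a 36.8-fold difference. These libraries held 23461499 and 9469638 counts, and replicate 2 had the lowest TMM factor of the series (0.63). No pair was close enough to be a single library deposited again, as their counts differed by more than sampling noise.

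ETV2, an ETS factor needed for the first endothelial and blood progenitors, switched on the endothelial genes at day 5 while the pluripotency genes stayed at levels not called different from the controls. All 33 endothelial genes tested rose (33 adjusted over the list alone). For each of the 22 lists, the count adjusted over the list alone follows in parentheses where it differs from the count adjusted over all genes. CDH5, the adhesion molecule of endothelial junctions, reached 920 ± 173 CPM against 0.375 ± 0.445 in the controls (SD, n = 2 and 6; log2 11.14, SE 1.2, edgeR adjusted p = 4.25e-05). PLVAP, a protein of endothelial diaphragms, stood at 762 ± 263 CPM, 2130-fold above the controls, MMRN1 at 151 ± 92.1 CPM (4830-fold) and CD34, a surface marker of endothelial and blood progenitors, at 247 ± 8.9 CPM (323-fold). ETV2 itself stood at 170 ± 33 CPM against 0.815 ± 0.155. POU5F1, the core pluripotency factor, was at 1660 ± 621 CPM against 1670 ± 275 (log2 -0.01, edgeR adjusted p = 1).

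In all, 1040 of 15620 genes were called with ETV2, 1002 higher and 38 lower. Of the arterial genes 10 of 13 rose (11 adjusted over the list alone), among them DLL4, a Notch ligand of arterial endothelium (174 ± 29.9 CPM, 482-fold), and the connexin GJA4 (205 ± 98.5 CPM, 99-fold). Of the venous and lymphatic genes 4 of 8 rose, with STAB1, a scavenger receptor of sinus endothelium, at 683 ± 413 CPM (412-fold). Of the hematopoietic regulators 7 of 22 rose (8 adjusted over the list alone), including TAL1 (68.4 ± 14.7 CPM, 139-fold) and LMO2 (106 ± 5.92 CPM, 62.6-fold), partners in 1 DNA-binding complex. Of the genes shared by blood cells 7 of 20 rose, such as LAPTM5, a lysosomal protein (121 ± 16.6 CPM, 251-fold). Among lineage genes, 2 of 25 erythroid, 3 of 22 megakaryocyte, 4 of 22 myeloid (5), 1 of 11 lymphoid (3) and 0 of 10 mast cell genes (1) rose. The megakaryocyte genes were F2RL2, a thrombin receptor, and MMRN1 and VWF, which also stand in the endothelial list.

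Primitive streak and mesoderm genes rose in 10 of 19 cases (13 adjusted over the list alone), with APLNR, the apelin receptor, at 89.9 ± 6.25 CPM (254-fold) and EOMES at 26.1 ± 5.36 CPM (79.9-fold). Endoderm genes rose in 5 of 12 cases (7), with GATA6 at 13 ± 4.7 CPM (58.4-fold). MEF2C, a muscle and endothelial regulator, led the 3 of 12 cardiac and skeletal muscle genes that rose (4; 78.8 ± 20.3 CPM, 118-fold). The intermediate filament gene VIM rose 7-fold to 1910 ± 415 CPM, as 1 of 2 mesenchyme genes of 18 that rose (2, with 1 fall). Interferon response genes rose in 11 of 17 cases (13), among them OAS1, a sensor of double-stranded RNA (4.13 ± 1.31 CPM, 57.7-fold), and IFI44L (11.2 ± 0.254 CPM, 1470-fold with a counting interval of 264 to 58200). In the p53 and stress list 2 of 18 rose, and in the HOXA cluster 1 of 9 (2). None of 20 pluripotency, 16 neuroectoderm, 12 trophoblast, 20 proliferation or 11 histone genes was called. Among the largest falls were JPH4, a junctophilin of neurons (12 ± 1.65 CPM against 59.7 ± 17.7), and GPC3, a glypican (49.2 ± 0.69 against 219 ± 122).

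With an estimated correlation the ETV2 calls of camera held for the endothelial (adjusted p = 0.00349), arterial (adjusted p = 0.0133), interferon (adjusted p = 0.0227) and primitive streak lists (adjusted p = 0.0449). Other adjusted p-values with an estimated correlation were 0.0507 for the venous, 0.0814 for the cardiac, 0.0869 for the regulator, 0.101 for the endoderm, 0.117 for the shared blood cell, 0.54 for the megakaryocyte and 0.589 for the myeloid list. The proliferation list lay lower by camera with the preset correlation (adjusted p = 0.0107) and not with an estimated one (adjusted p = 0.542). Against the lone day 5 control, 81 genes were called, 11 endothelial and 0 interferon genes among them, although 33 of 33 and 16 of 17 members lay above it. Against the untransduced day 7 pair 429 genes were called, by limma 644, and without ETV2 replicate 2 there were 640, with 6 primitive streak, 0 HOXA and 0 lymphoid genes risen. Without ETV2 replicate 1, 1 erythroid and 2 lymphoid genes rose. Of the myeloid genes 2 rose without ETV2 replicate 2 or untransduced day 1, day 3, day 5 or day 7 replicate 1. Of the mesenchyme genes 1 rose without either ETV2 library, the vector control or untransduced day 7 replicate 1. Of the stress genes 0 rose without either ETV2 library or untransduced day 7 replicate 2, and 1 without the vector control or untransduced day 3, day 5 or day 7 replicate 1. A pluripotency gene rose without untransduced day 1 or day 7 replicate 1, a neuroectoderm gene without the latter and a mast cell gene without the vector control. By DESeq2 82.5% of the calls were higher instead of 96.3%.

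**Figure D1:**
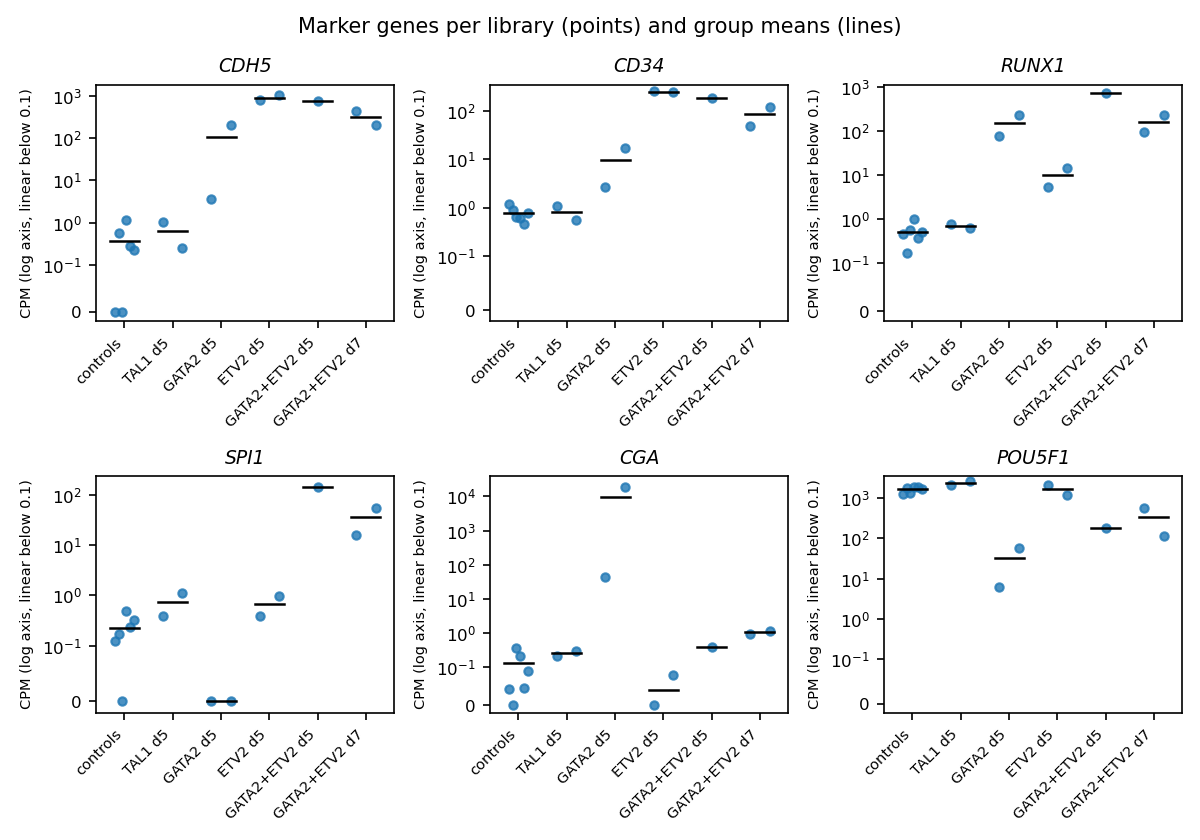
CPM of 6 marker genes in each library (points, log axis that is linear below 0.1) and the mean of each group (lines) for the 6 controls, TAL1, GATA2 and ETV2 at day 5, and GATA2 with ETV2 at days 5 and 7. CDH5 lay at 920 ± 173 CPM with ETV2 and at 0.375 ± 0.445 in the controls, while the CGA levels of the GATA2 libraries lay far apart.

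GATA2, a zinc finger factor of blood stem cells that also acts in placenta, mast cells and other tissues, lowered pluripotency transcripts and raised placental and mesenchymal ones at day 5. None of these list calls held with an estimated correlation (adjusted p = 0.157 for the pluripotency, 0.0869 for the trophoblast and 0.33 for the mesenchyme list). All 12 trophoblast genes tested rose (12 adjusted over the list alone). CGA, the alpha subunit of the gonadotropins, averaged 9510 ± 13400 CPM against 0.128 in the controls (SD, n = 2; log2 16.40), and CYP19A1, the estrogen-making aromatase, 1260 ± 1760 CPM (12000-fold). The SDs are as large as the means because the replicates lay far apart, yet each named gene was past the threshold in the fit. Of the pluripotency genes 16 of 20 fell (17 adjusted over the list alone). TDGF1, a Nodal co-receptor, stood at 11.1 ± 12.8 CPM against 733 ± 145 (log2 -6.10, edgeR adjusted p = 0.000303), ZIC3 at 2.64 against 138 and PRDM14 at 2.67 against 125.

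In total 5122 genes were called with GATA2, 3261 higher and 1861 lower, and GATA2 itself averaged 3290 ± 4400 CPM (1180-fold). Mesenchyme and smooth muscle genes rose in 13 of 18 cases and fell in 1 (14 rises adjusted over the list alone), with the fibrillar collagen COL3A1 at 6650 ± 9080 CPM (38200-fold). Endoderm genes rose in 10 of 12 (11), among them GATA6 (52.2 ± 7.69 CPM, 234-fold) and HNF4A, a liver and gut regulator (11.3 ± 8.39 CPM, 354-fold). Cardiac and skeletal muscle genes rose in 8 of 12, and primitive streak and mesoderm genes in 9 of 19, led by HAND1 (480 ± 604 CPM, 1400-fold). Endothelial genes rose in 18 of 34 and fell in 1 (20 rises adjusted over the list alone), with CDH5 at 106 ± 144 CPM (281-fold). Arterial genes rose in 6 of 13, such as the Notch target HEY1 (194 ± 61.1 CPM, 178-fold), and venous and lymphatic genes in 4 of 8 (4, with 1 fall), led by NR2F2, a nuclear receptor of venous identity (360 ± 265 CPM, 1800-fold).

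Among blood genes, GATA2 raised 8 of 21 regulators, including RUNX1, the master factor of blood stem cell emergence (151 ± 106 CPM, 298-fold), and 4 of 20 genes shared by blood cells, of which 1 fell. Erythroid genes rose in 7 of 25 cases, megakaryocyte genes in 5 of 22 (4 adjusted over the list alone) and mast cell genes in 1 of 9. Myeloid genes rose in 8 of 22 and fell in 1, with CSF1R, the receptor of macrophage growth factor, at 11.5 ± 2.73 CPM (239-fold). Of all 15620 genes, 3261 rose with GATA2. Camera with the preset correlation did not place the regulator, shared blood cell, erythroid, megakaryocyte, mast cell or myeloid list higher than other genes (adjusted p of 0.069 or more). LCK, a T cell kinase also found in stem cells, was the 1 lymphoid gene of 11 that fell (0.555 CPM against 49.4). Of 20 proliferation genes 8 fell (9, with 1 rise), among them the replication licensing gene MCM5 (98.4 ± 1.28 CPM against 324). In the p53 and stress list 12 of 18 rose, with ATF3 at 1090 ± 1390 CPM (34.4-fold), and 6 of 9 HOXA genes rose. Interferon genes rose in 3 of 17 and fell in 1, neuroectoderm genes rose in 1 of 16 and fell in 2, and 1 of 11 histone genes rose (0).

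No other GATA2 list call held with an estimated correlation either: adjusted p = 0.0869 for the cardiac, 0.123 for the endoderm, 0.338 for the proliferation, 0.339 for the endothelial, 0.343 for the arterial, 0.444 for the primitive streak and 0.573 for the p53 and stress list. The count of called genes was 988 against the lone day 5 control, with 49.6% higher instead of 63.7%, and 2472 against the day 7 pair. By limma on TPM 40.8% of the calls were higher. With 1 library left out at a time, 10 to 12 trophoblast genes rose and 12 to 17 pluripotency genes fell. Without replicate 2, 7 endothelial, 3 arterial, 1 venous, 2 shared blood cell, 2 megakaryocyte and 0 stress genes rose and 5 proliferation genes fell, and the log2 changes of the stress genes DDIT3, GDF15 and HMOX1 were below 0. Without replicate 1, 6 endoderm, 5 primitive streak, 5 cardiac, 2 erythroid and 0 HOXA genes rose, 14 proliferation genes fell, and HOXA1 and HOXA10 were below 0. Small counts moved too. Without replicate 2, 2 neuroectoderm and 0 histone genes rose, 3 regulators and 2 venous, 2 myeloid, 2 lymphoid, 2 interferon and 1 neuroectoderm genes fell, and no mesenchyme or endothelial gene did. Without replicate 1, 3 proliferation, 2 neuroectoderm and 1 lymphoid genes rose, 3 stress and 1 venous genes fell, and no interferon or endothelial gene did. Among the controls, the endothelial fall was lost without untransduced day 1, day 3, day 7 replicate 1 or the vector control, and the mesenchyme fall without day 1, day 3 or day 5. Of the shared blood cell genes 2 fell without untransduced day 1, day 7 replicate 2 or the vector control. Without day 7 replicate 1, 2 neuroectoderm genes rose and 1 primitive streak gene fell, without day 1, 2 histone and 1 lymphoid genes rose, and without day 3, 1 proliferation gene rose.

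TAL1 alone, a helix-loop-helix factor needed for all blood formation, left the transcriptome close to the controls at day 5. TAL1 rose to 652 ± 245 CPM from 0.492 ± 0.292 (SD, n = 2 and 6; log2 10.43, SE 0.739, edgeR adjusted p = 4.2e-05) and was the only gene of 15620 called. No member of any of the 22 lists other than TAL1 was called. The endothelial receptor KDR stood at 216 CPM against 162 in the controls, EGFL7 at 36.1 against 36.9 and POU5F1 at 2380 ± 348 against 1670 ± 275. There were 180 genes at an unadjusted p under 0.05, 4 were called by DESeq2 and 1 by limma. Camera placed the endothelial list higher with the preset correlation (adjusted p = 2.37e-05) and not with an estimated one (adjusted p = 0.33), and 2 of its genes passed adjusted over the list alone. The endoderm, mesenchyme and stress lists likewise lost their higher placement (adjusted p = 0.33, 0.409 and 0.404 with an estimated correlation).

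The 24 factors in 1 library ranged from 0 to 2348 genes called. These differences have no replicate check, and each library was assumed to vary like the controls and duplicated groups. With 5 or more endothelial genes risen there were 7 factors, and with 5 or more hematopoietic genes 12. These counts were not tested against the share of all genes called higher. EGR1 raised 704 of 15620 genes and 5 of 105 hematopoietic ones, whereas ERG raised 315 and 17. A count near 5, or a larger one where many genes rose, may thus be no more than that share. ERG, an ETS factor of endothelium, raised 25 of 33 endothelial genes (31 adjusted over the list alone), with CDH5 at 522 CPM (1390-fold), PLVAP at 447 CPM (1250-fold) and ROBO4 at 30.8 CPM (at least 1350-fold), and 17 of 105 hematopoietic genes. FLI1, a related factor collected at day 3, raised 10 of 33 endothelial genes (18), such as the junction protein ESAM (63.9 CPM, 96.3-fold) and SOX18 (36.8 CPM, 127-fold), although only 35 genes were called in all. GATA3 raised 11 endothelial (18) and 20 hematopoietic genes, HHEX 10 and 15, RUNX1c 9 (12) and 16, EGR1 7 and 5, and CEBPa 5 and 20.

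CEBPa, a myeloid factor, raised S100A9, a calcium-binding protein of neutrophils, to 2510 CPM (329000-fold with a counting interval of 59100 to 1.3e+07), and CYBB and NCF2, parts of the phagocyte oxidase, to 42.8 and 48 CPM (202-fold and 120-fold). With HHEX the integrin ITGB3 of platelets stood at 81.3 CPM (230-fold) and RUNX1 at 110 CPM (217-fold), and with RUNX1c ITGB3 stood at 129 CPM (367-fold) and FCER1G at 50.5 CPM (197-fold). With GATA3 the placental CGA rose to 678 CPM (5320-fold) beside CSF1R at 42 CPM (873-fold). SPI1 raised 12 of 17 interferon genes (17), with OAS1 at 21.1 CPM (295-fold), and 6 hematopoietic genes. Interferon genes also rose with FOXF1, 9 in number (12), and with FOXC2 (12), HHEX (8) and RUNX1c (8), 7 in each, whereas 0 were called with ERG (1). GATA1 and CDX2 raised 8 hematopoietic genes each, FOXC2 and RUNX1b 7 each, FOXF1 6, HAND1 3, FLI1 2 and ETV6 1, and CDX2 raised HOXC6, a posterior patterning gene, from 0 to 79.2 CPM (at least 3470-fold).

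**Figure D2:**
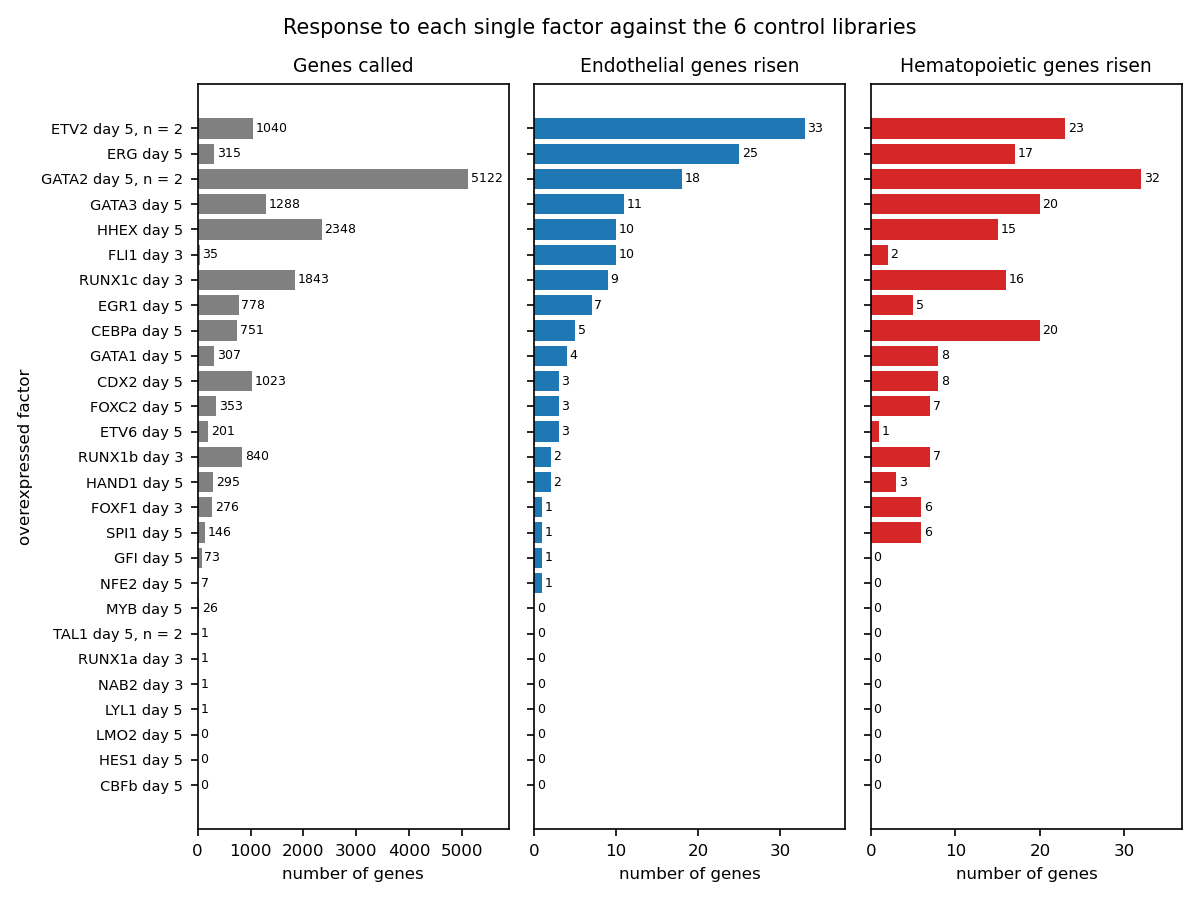
Numbers of genes called, of endothelial genes risen and of hematopoietic genes risen with each single factor against the 6 controls (bars, number of genes), for 27 factors of which TAL1, GATA2 and ETV2 have 2 libraries. ETV2 and ERG raised 33 and 25 endothelial genes, and 7 factors had 1 or 0 genes called.

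Little or nothing was called with other factors. Among the 24, the libraries labelled CBFb, HES1 and LMO2 gave 0 calls each by edgeR (90, 138 and 75 genes at an unadjusted p under 0.05), and those of LYL1, NAB2 and RUNX1a gave 1 call each, the factor itself (201, 147 and 62). The first 3 gave 0 calls each by limma and 1, 2 and 1 by DESeq2. In their libraries CBFB (25.2 CPM) and HES1 (16.3 CPM) lay within the control range, and LMO2 reached 14 CPM. The lack of calls therefore does not show that these factors are inactive. NFE2 gave 7 calls, MYB 26 and GFI 73, and 14 of the 24 gave 100 or more, up to 2348 with HHEX. Against controls of the same day no factor kept 5 endothelial or 5 hematopoietic genes, where a lone library was set against 1 control. Against the day 7 pair 3 and 5 factors did, and by limma 6 factors kept 5 hematopoietic genes.

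GATA2 with ETV2 at day 7 raised endothelial, blood, muscle and mesenchymal transcripts. With an estimated correlation the list calls held for the endothelial and cardiac lists (adjusted p = 0.0173 each) and the regulators (adjusted p = 0.0449), and not for the mesenchyme (adjusted p = 0.178), shared blood cell (0.0868), erythroid (0.0869), myeloid (0.123), megakaryocyte (0.188) and mast cell lists (0.0531). Of 33 endothelial genes 32 rose (33 adjusted over the list alone), with CDH5 at 324 ± 164 CPM (SD, n = 2; 864-fold). Of 21 hematopoietic regulators 20 rose and 1 fell. RUNX1 stood at 164 ± 100 CPM (323-fold; log2 8.34). GFI1B, a transcriptional repressor that acts within the erythroid and platelet lineages, stood at 82.4 ± 108 CPM (at least 3610-fold). Genes shared by blood cells rose in 14 of 20 cases and fell in 1 (15 rises adjusted over the list alone), with LAPTM5 at 234 ± 117 CPM (486-fold). Megakaryocyte genes rose in 19 of 22 (20), among them PLEK, the platelet protein pleckstrin (194 ± 263 CPM, 4220-fold). Erythroid genes rose in 15 of 25 (17), with the fetal globin HBG2 at 53.7 ± 70.1 CPM (959-fold), and myeloid genes in 15 of 22, with CSF1R at 44.7 ± 39.3 CPM (929-fold). Mast cell and related genes rose in 8 of 9, such as HDC, the histamine-making enzyme (48 ± 55.1 CPM, 326-fold). Lymphoid genes rose in 2 of 11 (3) and fell in 1.

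A total of 2764 genes were called at day 7, 2080 higher and 684 lower. GATA2 stood at 524 ± 82.7 CPM and ETV2 at 140 ± 18 CPM. All 9 HOXA genes tested rose, including HOXA9, a factor of definitive blood progenitors (6.99 ± 0.919 CPM), and HOXA10 (9.8 ± 0.0146 CPM). Arterial genes rose in 9 of 13, with the connexin GJA5 at 73.5 ± 9.12 CPM (38.1-fold), and venous and lymphatic genes in 5 of 8 (6, with 1 fall). Primitive streak and mesoderm genes rose in 13 of 19 (15), with HAND1 at 440 ± 160 CPM (1290-fold), cardiac and skeletal muscle genes in 7 of 12, with the cardiac factor NKX2-5 at 20.9 ± 2.74 CPM (94.7-fold), endoderm genes in 9 of 12 (10) and mesenchyme genes in 12 of 18 (14), with COL3A1 at 3410 ± 4020 CPM (19600-fold). Interferon genes rose in 14 of 17 (15), with OAS1 at 10.8 ± 5.78 CPM (151-fold), and trophoblast genes in 4 of 12. Neuroectoderm genes rose in 2 of 16 and fell in 1, 3 of 20 proliferation genes fell (4), and 0 of 18 p53 and stress and 0 of 11 histone genes were called. Pluripotency genes fell in 10 of 20 (11), with DNMT3B, a DNA methyltransferase of early embryos, at 335 ± 271 CPM against 3070 ± 999.

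No other day 7 list call held with an estimated correlation. Adjusted p-values were 0.0507 for the primitive streak, 0.0514 for the HOXA, 0.0531 for the arterial and venous, 0.0544 for the interferon, 0.101 for the endoderm, 0.33 for the pluripotency and 0.444 for the proliferation list. Against the 3 controls of day 7 there were 1789 calls, with 31 endothelial genes risen but 3 pluripotency genes risen and 3 fallen, and against the untransduced day 7 pair 875. Without replicate 2 the count was 1110, with 13 regulators, 11 megakaryocyte, 11 erythroid, 11 myeloid, 9 interferon, 6 endoderm, 6 mesenchyme, 4 mast cell and 2 trophoblast genes risen and 0 pluripotency, 0 proliferation, 0 neuroectoderm, 0 lymphoid and 0 regulator genes fallen, and by DESeq2 64.9% of the calls were higher instead of 75.3%. Without replicate 1, 0 neuroectoderm genes rose, and without untransduced day 1, 3 stress genes did. Of the lymphoid genes 1 rose without replicate 2, untransduced day 3 or either untransduced day 7 library, and no shared blood cell gene fell with any 1 library left out except untransduced day 5.

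**Figure D3:**
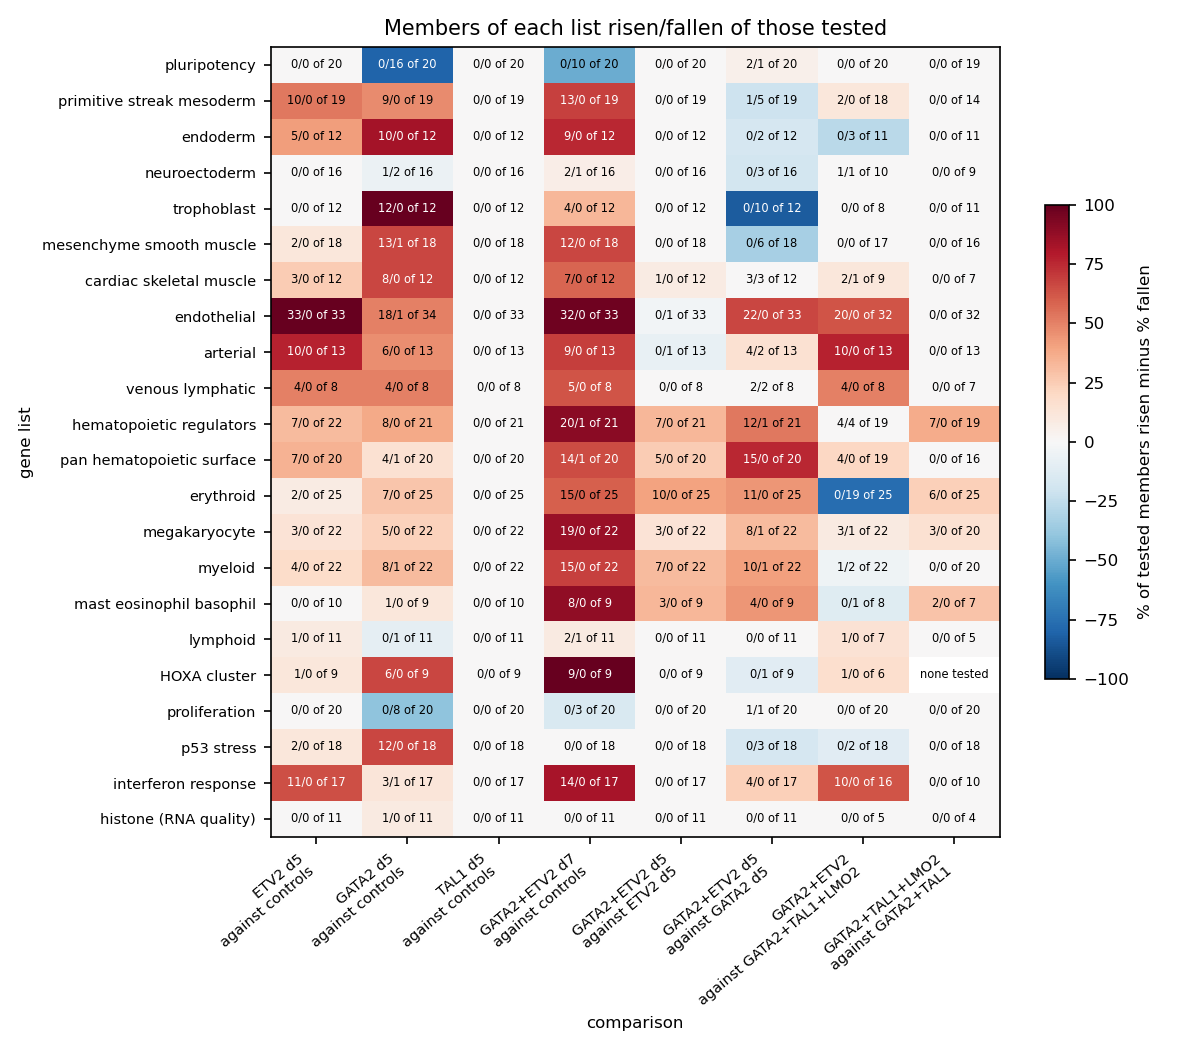
Members of each of the 22 gene lists called higher and lower of those tested (numbers in the cells) in 8 comparisons (columns), colored by the percentage risen minus the percentage fallen. ETV2 raised 33 of 33 endothelial genes and GATA2 raised 12 of 12 trophoblast genes.

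Some blood genes were higher at day 5 with GATA2 and ETV2 together than with ETV2 alone, while 32 of 33 endothelial genes were not called different. These blood gene calls were lost without ETV2 replicate 1. With an estimated correlation the erythroid and mast cell lists (adjusted p = 0.0173 each) and the regulators (adjusted p = 0.0288) held, and the shared blood cell (adjusted p = 0.0507), myeloid (0.0514) and megakaryocyte lists (0.257) did not. The comparison set 1 library of GATA2 with ETV2 against 2 of ETV2, so the difference has no replicate check on the combined side. RUNX1 stood at 755 CPM against 9.83 ± 6.4 (SD, n = 2; log2 6.27, SE 0.851), and SPI1, the master factor of myeloid cells, at 143 against 0.676 CPM (211-fold). Of the erythroid genes 10 of 25 rose (13 adjusted over the list alone), with the surface protein GYPA at 59 CPM (428-fold). Of the regulators 7 of 21 rose (14, with 1 fall), of the myeloid genes 7 of 22 (14), with CSF1R at 275 CPM (482-fold), and of the genes shared by blood cells 5 of 20 (11), with SPN, the sialomucin CD43, at 520 CPM (57.6-fold). Of the mast cell genes 3 of 9 rose (7), with CPA3 at 137 CPM (at least 1870-fold), and of the megakaryocyte genes 3 of 22 (9), with the platelet integrin ITGA2B at 765 CPM (141-fold).

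Only 1 of 33 endothelial genes was called, SOX17, which fell to 4.74 CPM from 56.5 ± 21.5, and 1 of 13 arterial genes, the netrin receptor UNC5B, fell to 36.3 CPM from 234 (5 falls). In all 221 genes were called, 135 higher and 86 lower. Of 12 cardiac and skeletal muscle genes 1 rose (2, with 1 fall), and no gene was called of the pluripotency, primitive streak, endoderm, neuroectoderm, trophoblast, mesenchyme, venous (2 falls), lymphoid (1 fall), HOXA, proliferation, stress, interferon or histone lists. POU5F1 stood at 178 CPM against 1660 ± 621, which was not called. Other adjusted p-values with an estimated correlation were 0.206 for the arterial, 0.264 for the primitive streak, and 0.41 for the pluripotency and neuroectoderm lists. The count was 1 without ETV2 replicate 1, with 0 blood genes risen, and 44 without replicate 2, with 5 erythroid, 5 regulator, 2 myeloid, 1 shared blood cell, 1 mast cell and 0 megakaryocyte genes risen, and no endothelial, arterial or muscle gene was called without either. Meanwhile limma called 415 genes and DESeq2 1316, 32.5% of them higher instead of 61.1%. With the GATA2 pair left out of the spread, an alternative chosen after seeing that this pair differed most, 808 genes were called, 47.3% of them higher.

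Set against GATA2 alone, the same day 5 library held endothelial and blood genes at higher levels and placental and mesenchymal genes at lower ones. With an estimated correlation the endothelial list held (adjusted p = 0.0449), and the blood lists (adjusted p of 0.0507 or more), the trophoblast (0.0869) and the mesenchyme list (0.33) did not. Of 33 endothelial genes 22 rose (24 adjusted over the list alone), with CLDN5, a tight junction protein, at 57.2 CPM (167-fold), and of the genes shared by blood cells 15 of 20 (17), with the adaptor LCP2 at 169 CPM (146-fold). Regulators rose in 12 of 21 cases and fell in 1 (14 rises), with VAV1, a signaling exchange factor of blood cells, at 218 against 1.36 CPM (159-fold), erythroid genes in 11 of 25 (13), myeloid genes in 10 of 22 with 1 fall (11 and 2), megakaryocyte genes in 8 of 22 with 1 fall (12 and 2) and mast cell genes in 4 of 9. Trophoblast genes fell in 10 of 12 cases (12), with CGA at 0.383 against 9510 CPM, and mesenchyme genes in 6 of 18 (9), with COL1A1 at 58.3 against 3280 CPM. HAND1 stood at 1.77 against 480 CPM as 1 of 5 primitive streak and mesoderm genes of 19 that fell, while 1 rose.

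Arterial genes went both ways (4 of 13 rose and 2 fell), as did venous genes (2 and 2 of 8), muscle genes (3 and 3 of 12, or 3 and 5 over the list alone), pluripotency genes (2 and 1 of 20) and proliferation genes (1 and 1 of 20). Endoderm genes fell in 2 of 12 cases (6 adjusted over the list alone), neuroectoderm genes in 3 of 16, stress genes in 3 of 18 and HOXA genes in 1 of 9 (0). Interferon genes rose in 4 of 17 (6), and 0 of 11 lymphoid (2) and 0 of 11 histone genes were called. In total 2091 genes were called, 937 higher and 1154 lower. GATA2 stood at 1360 against 3290 ± 4400 CPM. Adjusted p with an estimated correlation was 0.0507 for the shared blood cell, 0.0514 for the regulators and the erythroid, 0.0714 for the mast cell, 0.228 for the myeloid, 0.257 for the endoderm, 0.33 for the megakaryocyte, 0.338 for the interferon, 0.508 for the neuroectoderm, 0.514 for the pluripotency and 0.576 for the stress list. The median log2 difference of all genes was 0.01, and -0.1 with median-ratio size factors, so small differences are relative to that shift. The count was 3934 without GATA2 replicate 1 and 3638 by DESeq2, with 31% higher instead of 44.8%, while limma gave 58.6% higher. Without replicate 1, 9 stress, 4 endoderm, 2 myeloid, 1 interferon, 0 megakaryocyte and 0 HOXA genes fell, 2 interferon, 2 stress and 0 primitive streak genes rose, pluripotency genes rose in 2 and fell in 2 cases and proliferation genes in 8 and 2. Without replicate 2, 11 mesenchyme, 5 endoderm, 5 muscle, 2 HOXA, 1 neuroectoderm and 0 myeloid genes fell, 1 lymphoid and 0 primitive streak genes rose, 9 pluripotency genes rose with 0 falls, and 0 proliferation genes were called.

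GATA2 with ERG, measured in 1 library at day 7 and so without a replicate check, raised 32 of 33 endothelial genes (33) and 52 of 104 hematopoietic genes. PLVAP stood at 408 CPM (1140-fold), MMRN1 at 50 CPM (1600-fold) and ROBO4, a guidance receptor of endothelium, at 36.3 CPM (at least 1590-fold). Of the regulators 15 of 21 rose and 1 fell, and of the HOXA genes 7 of 9 rose (9). Endoderm genes rose in 10 of 12 (11), trophoblast genes in 8 of 12 (9) and mesenchyme genes in 8 of 18 (11), with COL3A1 at 1690 CPM (9710-fold), while pluripotency genes fell in 12 of 20 (15). GATA2 with TAL1 at day 7, also 1 library, raised 23 of 33 endothelial (26), 9 of 12 trophoblast (11), 9 of 12 endoderm (11) and 12 of 18 mesenchyme genes, with CGA at 1850 CPM (14500-fold), and 13 of 20 pluripotency genes fell (16). TAL1 itself stood at 8.68 CPM in this library, against 268 CPM at day 5 and 0.492 ± 0.292 in the controls. This library lay nearest to GATA2 with ERG at day 7 (r = 0.951 across genes). Whether its changes depend on TAL1 was not tested.

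Against the controls, endothelial and blood genes were both called higher from day 1 of the courses, and no test compared their order. CD34, VWF, MMRN1 and, where it was not overexpressed, TAL1 count in both sets, so the counts can partly repeat each other. With GATA2 and ETV2, 19 endothelial genes (27) were called higher at day 1 and 31, 31, 32 and 32 of 33 at days 2 to 5 (32 at each), while hematopoietic genes numbered 17, 36, 48, 58 and 73 of 104. CDH5 stood at 165 CPM at day 1 and 1080 at day 2, and RUNX1 at 23.2, 115, 297, 413 and 755 CPM over days 1 to 5. With GATA2, TAL1 and LMO2, hematopoietic genes numbered 14, 29, 49, 68 and 78 of 102 and endothelial genes 5, 10, 15, 21 and 21 of 33 (6, 11, 18, 26 and 23). GATA1 stood at 5.16, 49.1, 78.8, 177 and 233 CPM, and 24 of 25 erythroid genes (25) were called higher at day 5. Each of these days is 1 library without a replicate check.

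The courses of GATA2 with ETV2 and of GATA2 with TAL1 and LMO2 differed in endothelial and erythroid genes. Neither list call held with an estimated correlation (adjusted p = 0.0923 and 0.0531), and leaving out 1 library gave 8 (without day 3 of either course) to 23 endothelial genes higher, with 11 to 13 without day 4 or 5 of either course, and 14 to 19 erythroid genes lower. Averaged over matched days, 20 of 32 endothelial genes were higher with ETV2 (27 adjusted over the list alone). GPR116, an adhesion receptor, stood at 162 ± 103 CPM against 2.12 ± 2.11 (SD over days, n = 7 and 6; log2 6.38, SE 0.799, edgeR adjusted p = 0.0036), CLDN5 at 52.7 against 1.52 CPM (34.7-fold) and CD34 at 145 ± 95.4 against 11.7 ± 12.4 CPM (12.3-fold). Of 25 erythroid genes 19 were lower with ETV2 (21). The embryonic globin HBE1 stood at 3.43 CPM with ETV2 against 1140 ± 1660 CPM with TAL1 and LMO2 (log2 -8.83, SE 0.759, edgeR adjusted p = 0.00109), HBZ at 6.1 against 1490 ± 2590 CPM, and KLF1, the erythroid master factor, at 16.3 ± 23.9 against 151 ± 121 CPM. GATA2 was at 892 ± 305 CPM with ETV2 and 1220 ± 501 CPM with TAL1 and LMO2, which was not called.

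Arterial genes were higher with ETV2 in 10 of 13 cases (11 adjusted over the list alone), with DLL4 at 61.8 against 2.82 CPM (21.9-fold) and NRP1, a semaphorin and VEGF receptor, at 199 ± 83.6 against 14.9 ± 8.85 CPM (13.4-fold). Venous and lymphatic genes were higher in 4 of 8 (5), with FLT4, the lymphatic VEGF receptor, at 281 ± 153 against 21.9 ± 14.4 CPM (12.8-fold). Regulators went both ways, with 4 of 19 higher, such as MECOM (31.8 against 3.22 CPM), and 4 lower, such as GATA1 (26.4 against 113 CPM). Interferon genes were higher in 10 of 16 (11), with OAS1 26.8-fold higher, and genes shared by blood cells in 4 of 19 (6). Megakaryocyte genes were higher in 3 of 22 (4) and lower in 1, myeloid genes higher in 1 (2) and lower in 2 of 22 (3), mast cell genes lower in 1 of 8 (2), lymphoid genes higher in 1 of 7 and HOXA genes in 1 of 6 (2). Primitive streak genes were higher in 2 of 18 (5), muscle genes higher in 2 and lower in 1 of 9, neuroectoderm genes 1 and 1 of 10, endoderm genes lower in 3 of 11, and stress genes lower in 2 of 18 (3), one of them GDF15 (42.6 against 129 CPM). No pluripotency, trophoblast (4 higher), mesenchyme, proliferation or histone gene was called.

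A total of 975 genes differed between the courses, 695 higher and 280 lower with ETV2. With an estimated correlation the venous list held (adjusted p = 0.0288), and adjusted p was 0.0814 for the arterial, 0.175 for the interferon, 0.215 for the stress, 0.244 for the proliferation, 0.339 for the endoderm, 0.372 for the mast cell, 0.508 for the primitive streak and 0.54 for the shared blood cell list. Leaving out any library of days 2 to 5 gave 413 to 595 calls. Over all 13 omissions, 6 (without day 4 of either course) to 10 arterial and 5 to 10 interferon genes were higher, with 5 or 6 interferon genes without any 1 library of days 2 to 5. From 0 (without day 3 of either course) to 4 regulators were higher, and 1 to 7 (without day 7 replicate 2 of the ETV2 course) lower. From 0 (without day 5 of either course) to 7 (without the floating cells of day 7) shared blood cell genes were higher. Without day 2, 3 or 5 of either course 0 lymphoid, 0 myeloid and 1 megakaryocyte genes were higher, and without day 2, 3 or 4 of either course 1 muscle gene was higher and 1 regulator, 1 myeloid and 0 megakaryocyte genes were lower. Without day 3 of either course 1 primitive streak gene was higher and 1 endoderm and 0 muscle genes were lower. Without day 4 or 5 of either course at most 1 primitive streak gene was higher, and without day 4 of either 1 megakaryocyte gene was higher and 1 mesenchyme gene lower. Without day 1 of either course 2 myeloid and 1 trophoblast genes were higher, and without day 1 or 5 of either 2 mast cell genes were lower. Without any 1 library of days 1 to 5, 1 stress and 0 neuroectoderm genes were lower. Without day 7 replicate 1 of the ETV2 course 6 megakaryocyte, 2 myeloid and 0 HOXA genes were higher and 2 megakaryocyte, 1 primitive streak and 0 neuroectoderm genes lower. Without its replicate 2, 1 megakaryocyte, 1 trophoblast and 0 HOXA genes were higher and 5 endoderm, 4 myeloid, 2 megakaryocyte and 2 mast cell genes lower. Without the floating cells 2 lymphoid, 2 trophoblast, 1 primitive streak, 1 mesenchyme, 1 mast cell and 0 HOXA genes were higher and 2 muscle, 1 mesenchyme and 1 primitive streak gene lower. DESeq2 called 1552 genes, a fit without the day term 499, and by limma 84.2% of the calls were higher instead of 71.3%.

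**Figure D4:**
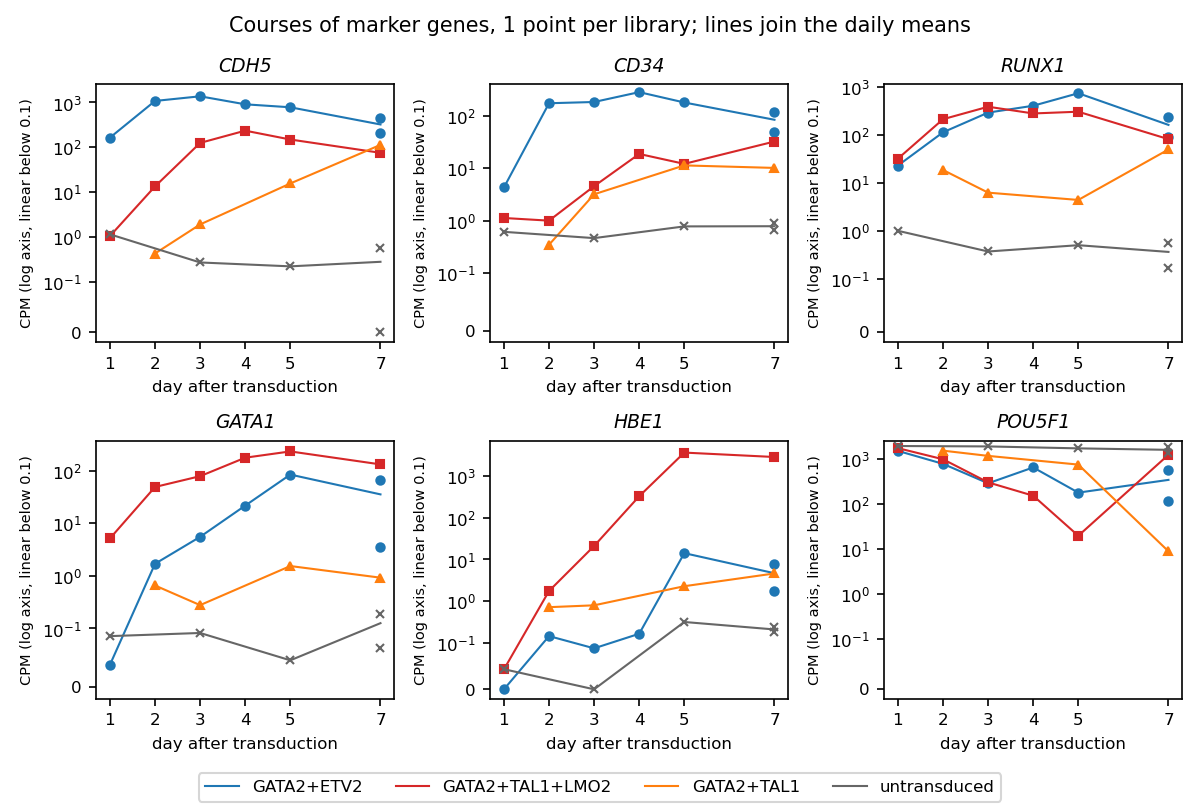
CPM (log axis that is linear below 0.1) of 6 marker genes by day after transduction, 1 point per library, with lines through the daily means of GATA2 with ETV2, GATA2 with TAL1 and LMO2, GATA2 with TAL1, and untransduced cells. HBE1 reached 3650 CPM at day 5 with TAL1 and LMO2 and 14.2 CPM with ETV2, and POU5F1 stood at 19.5 CPM at day 5 and 1240 CPM in the floating cells of day 7.

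Some erythroid, megakaryocyte and mast cell genes were higher in the course of GATA2 and TAL1 with LMO2, an adaptor that joins TAL1 and GATA proteins, than in that without it. No list call held with an estimated correlation (adjusted p of 0.0507 or more), and no gene was called without any 1 of the 6 libraries of days 2, 3 and 5. By the labels, the day 7 library with LMO2 was of floating cells, while the label of that without LMO2 does not say so. At days 2, 3, 5 and 7 together, GYPA stood at 336 ± 258 CPM with LMO2 and 0.45 ± 0.447 CPM without (SD over days, n = 4 and 4; 747-fold, log2 9.75, SE 0.68, edgeR adjusted p = 0.018). CA1, an erythrocyte carbonic anhydrase, stood at 236 ± 117 against 0.663 CPM (357-fold) and EPB42, a red cell membrane protein, at 55.1 CPM (1970-fold with a counting interval of 674 to 9560). Of 25 erythroid genes 6 rose (22 adjusted over the list alone). Of 19 regulators 7 rose (14), with GATA1 at 123 ± 80.6 against 0.85 ± 0.532 CPM (145-fold) and GFI1B at 119 ± 66.8 against 0.415 CPM (286-fold). Of 20 megakaryocyte genes 3 rose (12), with GP1BA, a von Willebrand factor receptor, at 106 CPM (50.9-fold), and of 7 mast cell genes 2 (6), with MITF at 38.2 ± 20.4 against 11.2 ± 5.45 CPM.

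In all 83 genes were called between these courses, 71 higher and 12 lower with LMO2, and 2482 had an unadjusted p under 0.05. The endocytic receptor LRP2 fell to 19.9 ± 10 CPM from 235 ± 90.5. No gene was called of the pluripotency, primitive streak, endoderm, neuroectoderm (1 lower), trophoblast (4 lower), mesenchyme, muscle (2 higher, 1 lower), endothelial (7 higher), arterial (1 higher, 2 lower), venous (1 higher), shared blood cell (9 higher), myeloid (10 higher), lymphoid, proliferation, stress (1 higher), interferon or histone lists (3 higher), and no HOXA gene was tested. LMO2 stood at 392 against 8.98 CPM, TAL1 at 1530 against 281 CPM and SPI1 at 103 against 0.609 CPM, none of them called. TAL1 in the course without LMO2 was 480, 366, 268 and 8.68 CPM at days 2, 3, 5 and 7, and no test separated the presence of LMO2 from the level of TAL1. Adjusted p-values with an estimated correlation were 0.0507 for the regulators, 0.0814 for the megakaryocyte, 0.0923 for the erythroid, 0.101 for the mast cell, 0.119 for the shared blood cell, 0.175 for the myeloid, 0.222 for the endothelial, 0.338 for the histone, 0.419 for the trophoblast, 0.529 for the primitive streak, 0.578 for the neuroectoderm and 0.66 for the stress list. The count was 0 without any 1 of the 6 libraries of days 2, 3 and 5, 303 and 265 without the day 7 library of either course, with 5 endothelial, 2 muscle and up to 2 shared blood cell genes higher, and 286 without day 7. In each of these fits without 1 day 7 library, 1 arterial, 1 mesenchyme and 1 interferon gene were also higher and 1 pluripotency gene lower. It was 48 by limma, 125 without the day term, and 1665 by DESeq2, with 48% higher instead of 85.5%.

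Within the course of GATA2 with ETV2, 78 of 14295 genes had a trend over days 1 to 7, 49 upward and 29 downward, and none did without day 7 replicate 2. HOXC6 rose by 3.85 and HOXB8 by 3.13 log2 units per day (SE of HOXB8 0.159, edgeR adjusted p = 0.0018), HOXA13 by 2.32, the mesoderm factor HAND1 by 1.83 and SNAI2, a regulator of epithelial to mesenchymal transition, by 1.45. The endoderm genes APOA1 and APOA2, apolipoproteins of liver and yolk sac, rose by 1.73 and 1.29, and the interferon genes IFI44L and OAS1 by 1.45 and 0.64. ETV2 itself fell by 0.34 per day (SE 0.0387, edgeR adjusted p = 0.0283). FOXI1 fell by 1.48 and the germ cell and early embryo gene DPPA3 by 0.78 per day. Members with trends were 3 of 18 primitive streak (8 adjusted over the list alone), 2 of 10 endoderm (4), 2 of 6 HOXA (6), 2 of 16 interferon (8), 1 of 7 trophoblast (3, with 1 fall), 0 of 20 megakaryocyte (9) and 0 of 32 endothelial genes. No gene was called of the cardiac (4 upward), mesenchyme (4 upward, 1 downward), erythroid (3 upward, 1 downward), myeloid (3 upward), neuroectoderm (2 upward) and lymphoid lists (1 upward) or of the remaining ones. Of the hematopoietic genes together 0 of 94 were called, and 9 upward and 1 downward passed adjusted over the list alone. No list call held with an estimated correlation, the adjusted p-values being 0.0612 for the cardiac, 0.101 for the HOXA, 0.257 for the interferon, 0.33 for the endoderm, 0.343 for the primitive streak and megakaryocyte lists, and 0.444 or more for the others. The count was 0, 2, 8, 13 and 26 without day 7 replicate 2, day 2, day 3, day 4 and day 1 in turn, 125 without day 5 and 393 without day 7 replicate 1. No primitive streak, trophoblast or interferon gene had a trend without day 7 replicate 2 or any 1 of days 1 to 4, and of the HOXA and endoderm genes at most 1 of each did. Without day 7 replicate 1, 5 megakaryocyte, 5 interferon, 2 shared blood cell, 2 erythroid, 2 myeloid, 1 endoderm, 1 mesenchyme and 0 HOXA genes rose and 1 pluripotency, 1 trophoblast and 1 mesenchyme gene fell. Without day 5, 2 trophoblast, 2 muscle, 1 erythroid, 1 mesenchyme, 1 neuroectoderm and 1 mast cell gene rose and 1 regulator fell. By limma it was 22, and by DESeq2 903.

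In the course of GATA2 with TAL1 and LMO2 a single gene had a linear trend over days 1 to 7, APOA1, which rose by 1.44 log2 units per day (SE 0.053, edgeR adjusted p = 0.00144). The globins HBG2 and HBZ had slopes of 3.17 and 3.31 that were not called. No other list gene had a called trend. Adjusted over the list alone, 16 of 25 erythroid, 10 of 19 megakaryocyte, 8 of 19 myeloid, 6 of 7 mast cell, 5 of 29 endothelial and 3 of 10 endoderm genes passed upward, as did 2 shared blood cell, 2 lymphoid, 2 interferon, 1 primitive streak, 1 mesenchyme and 1 histone gene. Downward, 2 neuroectoderm, 2 mesenchyme, 1 pluripotency, 1 venous and 1 myeloid gene passed. Adjusted p with an estimated correlation was 0.264 for the erythroid, 0.0507 for the megakaryocyte and 0.0987 for the mast cell list, 0.182 for the endothelial list and 0.187 or more for the others. The course was not a straight line: POU5F1 went from 1740 CPM at day 1 to 19.5 at day 5 and stood at 1240 CPM in the floating cells of day 7, where HBE1 was at 2860 CPM. Without that library 4363 genes had a trend, among them 21 erythroid and 15 endothelial genes upward and 15 pluripotency genes downward. The count was 847 by limma, 1621 by DESeq2, 215 on the log2 of the day and 27 without the filter on low counts.

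In untransduced cells 8 of 13498 genes had a trend over days 1 to 7. BST2, an interferon-induced membrane protein, rose by 0.61 log2 units per day, and SPP1, ACSS2, HMOX1 and FLNC fell by 0.65, 0.64, 0.53 and 0.51 (edgeR adjusted p = 0.042 each). HMOX1 was the 1 stress gene of 18 with a trend (2), and no gene of another list had one. Adjusted over the list alone, 2 primitive streak genes of 7, 2 regulators of 11 and 1 shared blood cell, 1 megakaryocyte, 1 lymphoid and 1 neuroectoderm gene passed upward, and 4 primitive streak, 4 of 12 shared blood cell, 3 of 4 histone, 1 endoderm, 1 endothelial, 1 erythroid, 1 interferon and 1 neuroectoderm gene downward. POU5F1 had a slope of -0.05 that was not called. The lists called by camera all lost the call (adjusted p of 0.222 or more with an estimated correlation). The count was 0 without either day 7 library, day 1 or day 3 and 137 without day 5, where 1 shared blood cell gene rose and 1 shared blood cell, 1 endothelial, 1 neuroectoderm and 1 histone gene fell. It was 0 by limma, 494 by DESeq2, 1 on the log2 of the day, 18 without the filter and 50 with the vector control.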

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

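The tests of a graded response to GATA2, of lentivirus over the single factors, of calls against depth by correlation and against each factor's own transcript, and of both sets of other splits were chosen only after the result was seen. So were the rule that a share must pass its bound by more than its binomial interval, the partial correlation, and the reading that a missed p excludes nothing, which replaced the earlier bound of p = 0.05 because a missed p in few libraries does not show absence of a relation.

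The 2 GATA2 libraries of day 5 differed at least 4-fold in 3130 genes. Depth as the cause was excluded: thinned to equal totals, 2937 genes still differed, against 941 in the next pair. A graded response to the GATA2 level, 36.8-fold apart in these libraries, may account for part of the difference and stays open. Of 2317 genes called higher with the low-GATA2 library alone, 26.4% (exact binomial interval 24.6 to 28.3) lay within or below the control range in the high-GATA2 library, too close to the bound of 25% to decide. That interval takes the genes as independent, which they are not, and covers no spread between libraries, so it could not decide in any case. The 2 GATA2 libraries were nearest to other samples, replicate 1 to GATA2 with TAL1 at day 7 (r = 0.947 across genes) and replicate 2 to GATA3 (r = 0.874). A difference in culture or a wrong label was not tested.

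Interferon genes rose with ETV2 in 11 of 17 cases. The values argue against lentivirus as such, acting alike in all transduced cells, as the cause. Of the 26 single factors other than ETV2, 6 had a list median log2 of 1 or more (23.1%, exact binomial interval 8.97 to 43.6, against a bound of 50%). The median was 3.08 with ETV2, -0.11 with TAL1 (range -1.1 to 1.43) and -0.07 in the vector control (range -0.8 to 0.97). At least 1 of these genes rose with 13 of the 24 factors in 1 library. This missed the bound of fewer than 12 set before the result was seen, so that rule left the question open. That bound asked for 1 gene, while lentivirus as the cause needs the list as a whole to rise. The binomial interval takes the chosen factors as random draws. The libraries labelled CBFb and HES1, counted among them, showed no rise of their own factor. A difference in virus dose was not tested. A response that accompanies the endothelial genes may contribute and stays open: over the 27 single factors the counts of both kinds of risen genes correlated (Spearman rho = 0.527, permutation p = 0.0055, adjusted 0.0165; Pearson r = 0.35, permutation p = 0.0599, adjusted 0.18, of 3 relations). Without ETV2 and ERG, rho was 0.586 and r 0.208, and at a given number of genes called rho was -0.138 (permutation p = 0.485), so the relation cannot be told apart from a general tendency of stronger responses.

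The number of genes called differed widely between single factors. Depth as the cause was excluded: after every library was thinned to the smallest total, 14 of 14 factors with 100 or more calls still had 100 or more. The 6 with 1 or 0 had at most 1, but thinning only removes reads, so that outcome adds no support. Thinning would not remove a batch that goes with depth, which was not tested. Calls and total counts gave Spearman rho = 0.369 (permutation p = 0.0765, adjusted 0.115; r = 0.185, permutation p = 0.402; without FOXC2 and CEBPa rho = 0.294, r = 0.244). The level of the factor's own transcript may matter and stays open (rho = 0.283, permutation p = 0.18, adjusted 0.18; r = 0.322, permutation p = 0.12; without HHEX and SPI1 rho = 0.21, r = 0.0451). RUNX1a gave 1 call at 1480 CPM of RUNX1 and RUNX1c gave 1843 calls at 1110 CPM, and their protein levels were not measured.

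Libraries were exchanged between courses within days only. Chance exchange of libraries within days was excluded for the courses of GATA2 with ETV2 and GATA2 with TAL1 and LMO2. Of the 96 splits of the 13 libraries, 1 (the real split) called 975 genes. The highest other called 604, and its first arm shared only 1 library with the real one, so it was nearly the mirror of the real split. The splits take the days of a course as separate draws. A difference in culture or virus shared by a whole course would also set the real split apart and was not excluded. The 8 libraries with and without LMO2 give 8 splits, too few for a share under 0.05. Of these, 1 (the real split) called 83 genes by edgeR, and the highest other called 0.

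Among the 6 controls 7 of 49 measures (the overexpressed genes, the lists and the total count) had 1 library far from the others, and chance gives about 1 in 20. The untransduced day 1 library stood apart for FOXC2 (0.565 CPM, others 0 to 0.0825) and for mean log2 CPM of the mesenchyme list (4.25, others 3.01 to 3.34), the cardiac list (-0.365, others -0.947 to -0.732), the HOXA cluster (-2.85, others -3.21) and the histone list (0.978, others -0.166 to 0.189). FOXC2 and the HOXA cluster lay near the floor, where a few reads can set 1 library apart and the rate of 1 in 20 need not hold. The second untransduced day 7 library stood apart for LYL1 (1.3 CPM, others 0.415 to 0.682), and the vector control for the megakaryocyte list (-0.299, others -0.737 to -0.637).

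Over days 1 to 5 the slope per day differed between the courses with ETV2 and with TAL1 and LMO2 for 416 of 14320 genes by edgeR, 326 with a higher slope with ETV2 and 90 with a lower one. A higher slope can be a smaller fall: that of L1TD1 was 0.92 higher with ETV2, and L1TD1 fell by 1.43 per day with TAL1 and LMO2. PLVAP had a slope 1.68 lower with ETV2 (log2 difference -1.68, SE 0.191, edgeR adjusted p = 0.0212) and HDC one 2.04 higher (SE 0.17, edgeR adjusted p = 0.0156). Days 1 to 5 were chosen after the floating cells of day 7 were seen to stand apart. Over days 1 to 7 edgeR called 0 genes, with 2767 of 14673 at an unadjusted p under 0.05.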

How the results depend on the processing

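The alternative that took the spread without the GATA2 day 5 pair was chosen after seeing the data, and all others were set before the data were examined. Of 187 alternative counts 105 lay within 1.5 times the reported one and 82 did not. Of 10123 alternative values of named genes 8599 kept direction and side of the threshold, 1167 lost the call, 135 gained it, 202 changed sign with a call in neither fit and 20 reversed with a call in at least 1 of the fits. Median-ratio size factors moved no count by over 1.5 times. The cause was not tested unless stated.

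Genes called with ETV2 numbered 1040, and 644 by limma, 81 with controls matched for day, 429 against the untransduced day 7 pair, and 640 (without ETV2 replicate 2) to 940 with 1 library left out. With GATA2 there were 5122, and 988 matched for day, 2472 against the day 7 pair, and 3805 to 5455 with 1 left out. With TAL1 there was 1, and 4 by DESeq2, 0 matched for day, and 1 to 2 (without untransduced day 1) with 1 left out. With GATA2 and ETV2 at day 7 there were 2764, and 1789 matched for day, 875 against the day 7 pair, and 1110 (without replicate 2) to 2741 with 1 left out. Fewer controls entered the matched and day 7 pair fits.

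GATA2 with ETV2 at day 5 against ETV2 gave 221, and 415 by limma, 1316 by DESeq2, 131 with the day 7 pair, 808 with the spread without the GATA2 pair, and 1 (without ETV2 replicate 1) to 44 (without replicate 2). Against GATA2 it gave 2091, and 3638 by DESeq2, 1349 with the day 7 pair, and 2215 to 3934 (without GATA2 replicate 1).

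The course with ETV2 against that with TAL1 and LMO2 gave 975, and 1552 by DESeq2, 499 with no day term, and 413 to 1105 with 1 library left out. The count was 595, 413, 498 and 545 without days 2 to 5 of the ETV2 course, and 593, 423, 510 and 529 without those of the other. With day as a factor, a day with 1 library per course drops out of a course comparison when either library is left out. Omitting that day from one course or the other is then much the same check. The course with LMO2 against that without gave 83, and 48 by limma, 1665 by DESeq2, 125 with no day term, 286 without day 7, and 0 to 303 with 1 left out. It was 0 by edgeR without day 2, 3 or 5 of either course, 303 without day 7 of GATA2 with TAL1 and 265 without day 7 of the course with LMO2. In simulated data of this contrast DESeq2 called 41 unchanged genes and edgeR 2.

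Day trends with ETV2 numbered 78, and 22 by limma, 903 by DESeq2, and 0 (without day 7 replicate 2) to 393 (without day 7 replicate 1). It was 26, 2, 8, 13 and 125 without days 1 to 5 in turn. With TAL1 and LMO2 there was 1, and 27 with no filter, 847 by limma, 1621 by DESeq2, 215 on the log2 of the day, and 1 to 4363 (without day 7). In untransduced cells there were 8, and 18 with no filter, 0 by limma, 494 by DESeq2, 1 on the log2 of the day, 50 with the vector control, and 0 (without either day 7 library, day 1 or day 3) to 137 (without day 5).

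Factors with 5 or more endothelial genes risen numbered 7, and 0 matched for day, 3 against the day 7 pair, and 6 to 7 with 1 control left out. For hematopoietic genes they numbered 12, and 6 by limma, 0 matched for day, 5 against the day 7 pair, and 10 to 12. Of the gene list tests 123 passed with the preset correlation, 12 with the estimated correlation and 81 with fry.

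With replicate number as a replicate block in the 10 numbered libraries, the counts were 435 with ETV2, 2692 with GATA2, 0 with TAL1 and 959 with GATA2 and ETV2 at day 7, and with no block in the same 10 libraries 432, 2461, 0 and 902. Same-numbered libraries deviated together in 7 of 10 pairs of groups (correlation over 0.1, range -0.105 to 0.53), not in all, so the numbers were not taken to pair them.

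With 1 library left out at a time, log2 changes with GATA2 ran from below 0 without replicate 1 for EVX1 (-1.07 to 7.97), HBG2 (-3.32 to 6.97), HBG1 (-1.7 to 6.96), HBZ (-2.46 to 5.26), HOXA10 (-1.7 to 7.24) and HOXA1 (-1.09 to 5.74), and from below 0 without replicate 2 for EPHB4 (-0.17 to 1.97), DDIT3 (-0.28 to 5.63), GDF15 (-0.78 to 5.92) and HMOX1 (-1.61 to 4.81). With the day 7 pair of GATA2 and ETV2, HTRA1 (1.12, against ETV2) and FOXF1 (2.26), PDGFRA (0.94), NKX2-5 (0.92) and HOXA9 (3.69, all against GATA2) reversed. Slopes with TAL1 and LMO2 that were not called over all days reversed, and were called, without day 7 for BMP4 (-1.11, up to 0.49 with another day left out), GABRP (-1, up to 0.63), TAGLN (-1.15, up to 0.14), MYL7 (-1.7, up to 0.34) and NOTCH1 (0.27, down to -0.27).

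Totals ran from 7648757 to 33613241. In simulated data of 1 library against 6 controls 2.99%, 26.9% and 71.2% of changes of 1, 2 and 3 log2 units were called. The simulation varied the size of the change and not depth, so a limit set by depth on genes of low level was not measured.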

Other observations

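The fit of the day trend without the floating cells was set before the data were examined, and the tests of its genes and lists were chosen only after the result was seen. Over days 1 to 5 of GATA2 with TAL1 and LMO2 (5 libraries), 4363 of 13747 genes had a trend, 1665 upward and 2698 downward. Among called genes with a mean TPM of at least 5, globin transcripts had the steepest rises, HBG1 by 4.31, HBZ by 3.92, HBG2 by 3.77 and HBE1 by 3.75 log2 units per day (SE of HBE1 0.0962, edgeR adjusted p = 0.000207). The pluripotency genes POU5F1 and NANOG fell by 1.54 and 1.47 per day, and CER1, an antagonist of Nodal made in early endoderm, fell by 3.6. Upward trends were found in 21 of 24 erythroid genes (23 adjusted over the list alone), 12 of 17 megakaryocyte (13), 13 of 18 myeloid (13), 13 of 17 shared blood cell (13) and 15 of 27 endothelial genes (18), and downward ones in 15 of 19 pluripotency (15) and 9 of 15 mesenchyme genes (9). With an estimated correlation adjusted p was 0.111 for the erythroid, megakaryocyte and pluripotency lists, 0.276 for the myeloid and shared blood cell lists, 0.341 for the endothelial and 0.426 for the mesenchyme list.

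The floating cells of day 7 stood apart from day 5 of the same course. POU5F1 was at 1240 CPM against 19.5 and NANOG at 31.1 against 1.67, while HBE1 was at 2860 against 3650 CPM and HBZ at 1700 against 6610. GATA2 was at 469 against 1620 CPM and TAL1 at 247 against 2300. This library lay nearest to ETV2 replicate 1 (r = 0.917 across genes). Each day is 1 library, and a mixture of cells was not tested.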
